A study of Mus musculus with 6 samples.

How the data were processed

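Total RNA was isolated with on-column DNase digestion and made into stranded whole-transcriptome libraries, per the labels' protocols, from 3 control and 3 stimulated samples of mouse PASMCs. Per the submitters' processing notes, the tools were FastQC, Trimmomatic 0.38, STAR 2.6.1d, featureCounts 1.6.3 and DESeq2 1.18.1, and the builds named were hg38, GRCh38 and mm10. The strand setting of the counting and the annotation release are not given in the sources used here, so levels of overlapping and antisense genes are uncertain.

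The deposited table holds a score per gene and library, which the values show to be read counts multiplied by 1 factor per library and rounded to whole numbers. In 4 of the 6 columns whole numbers are skipped at regular steps, as multiplication by a factor above 1 gives. The factor was estimated from skipped or doubled numbers as 1.07, 0.99 and 1.03 for control replicates 1 to 3 and as 1.32, 1.14 and 0.584 for the stimulated ones. It is least certain for control replicate 2. A factor under 1 merges neighbouring counts, so the reads were not recovered and count models were not used. Every gene row reaches at least 3 in some library. No 2 libraries were identical. Stimulated replicate 3 holds 2.33 times the reads of the shallowest library, which gives its low values less counting error.

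The design fixed before the data were examined assumed raw counts, with a count model as the main test. Because the values are normalized, its written fallback was used: limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1), for the 21743 genes with a mean of at least 1 over the 6 libraries (42 were left out), treatment as the only term, and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of genes with low values. The residual degrees of freedom were 4. Of the gene identifiers, 21747 of 21785 matched GENCODE M21 (mm10), and 15 rows share a symbol with another row. The gene lists were fixed before the data were examined, 27 for testing and 1 of sex-linked genes as a check of the samples. Each was tested with limma camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. No list passed with an estimated correlation (lowest adjusted p = 0.322; 2 lists had an unadjusted p under 0.05), 4 passed fry for 1 direction and 18 for either direction. Fry does not compare a list with other genes. On the sex-linked list, Xist was at 9 or less and Ddx3y at 1986 or more in each library.

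Genes are named by a rule set before the data were examined. It takes the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out unnamed gene models, pseudogenes and small RNA genes. It adds up to 3 members per list past the threshold with the smallest p, or 1 if none passed, and a fixed set of BMP pathway and contractile genes. Some genes that the rule takes are not reported here.

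Replicate numbers are shared by both groups in the labels. Over 13185 genes with a mean of at least 50, deviations from the group means correlated by 0.747, 0.741 and 0.218 between same-numbered libraries, each over 0.1, so the numbers were taken to pair the samples; the labels do not say what a number stands for. For replicate 3 the pairing is weak, since control replicate 3 correlated more with stimulated replicate 1 (0.287). The alternatives were other scalings, filters and pseudocounts, limma-voom, a replicate block and leaving out each library. Trimmed-mean (TMM) scaling, leaving out both replicate 2 libraries and equal totals together with the block were added after seeing the data. The fit was tested on simulated data for this comparison, with 200 of the genes changed and 21593 genes run. It called 68% of genes changed by 1 and 83% of those changed by 2 on the log2 scale, and 8 unchanged genes, 5.03% of its calls. The changed genes had a mean of at least 50, and each gene was drawn independently, without differences by replicate number. These rates therefore do not cover low genes or the shared deviations of the real libraries. Gene families described in the closing section were chosen after the results were seen.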

Results

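Gene expression was measured by sequencing of total RNA from mouse pulmonary arterial smooth muscle cells (PASMCs), the contractile cells of the lung artery wall, which were grown out from lungs of C57BL/6 mice. After 48 h in medium without supplements, 3 samples were stimulated for 6 h with bone morphogenetic protein 9 (BMP9, 1 ng/mL) and BMP10 (5 ng/mL), circulating ligands of the TGF-beta family, and 3 control samples were not. The deposited table held normalized read counts for 21785 genes, and these sum to between 27295973 and 31903795 per library. From the steps in the values, the reads behind them were estimated at 26.4, 27.6 and 27.3 M for control replicates 1, 2 and 3 and at 23.3, 28.0 and 54.4 M for stimulated replicates 1, 2 and 3. All levels below are normalized read counts given as mean ± SD (n = 3 per group). Changes are on the log2(value + 1) scale ± SE, stimulated minus control, with adjusted p-values from limma with Benjamini-Hochberg adjustment. The labels do not say whether the samples came from separate cultures or animals, so p-values measure only the spread between these samples. All 22 endothelial markers were highest in replicate 2 of both groups (median 3.65-fold in controls and 3.63-fold in stimulated samples). This argues against a purely technical spread for that replicate number. Between replicates 1 and 3 the spread may be technical.

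The comparison asks which genes change in PASMC cultures given BMP9 and BMP10, and among them which belong to the contractile apparatus. The cultures also held transcripts of other cell types, so neither a direct action nor the cell of origin can be read from it. Of 21743 genes tested with limma, 2905 changed at an adjusted p under 0.05, of which 1873 rose and 1032 fell. Among them, 542 rose and 404 fell by at least 1 on the log2 scale. The groups did not overlap for any of the 2905 genes, and they did not overlap for 33.2% of all genes tested, against 10% by chance for 3 against 3 unpaired libraries. The pairing by replicate number may change that chance share. Protein-coding genes made up 2684 of the changed genes. With the replicate number as a block, because the numbers paired the samples, limma called 5837 genes, 3232 higher and 2605 lower. The split between rises and falls moved with some scalings: 64.5% of the changed genes rose with the values as deposited, 64.3% with relative log expression (RLE) factors, 64.6% with trimmed-mean (TMM) factors, 51.2% with upper-quartile factors (1420 rose, 1352 fell) and 33.4% with equal library totals (1135 rose, 2265 fell). RLE factors hardly changed the deposited values, so that share is not a separate check. The median log2 change of all genes was -0.03 as deposited, -0.11 with upper-quartile factors and -0.20 with equal totals. Leaving out control replicate 1, control replicate 3 or stimulated replicate 3 left 1164, 1163 and 917 changed genes.

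**Figure D1:**
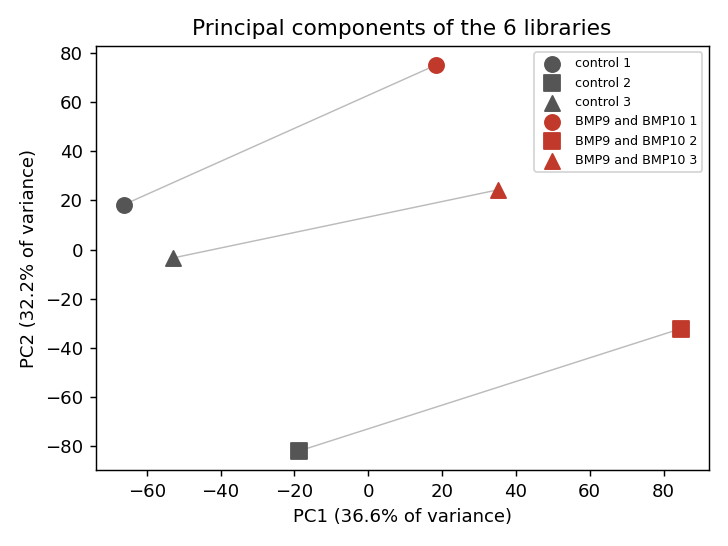
Each point is 1 library, placed by the first principal component (x axis, 36.6% of variance) and the second (y axis, 32.2%) of the log2 values. Grey points are controls, red points are stimulated libraries, and lines join libraries with the same replicate number; each stimulated library lies to the right of and above its control, and both replicate 2 libraries lie lowest.

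Most listed genes of the canonical BMP response rose. Of 24 tested members of the list of BMP-SMAD1/5 response genes, 15 rose, none fell and 9 did not pass the test (18 rose when adjusted over the list alone), with a median log2 change of 1.85. The inhibitor of differentiation genes, direct targets of BMP-activated SMADs, rose by 2.01 ± 0.21 for Id1 (551 ± 129 to 2220 ± 461, limma adjusted p = 0.00217), 2.48 ± 0.16 for Id2, 2.33 ± 0.28 for Id3 and 2.30 ± 0.53 for Id4. The inhibitory SMAD genes, which feed back on the pathway, rose from 232 ± 54.9 to 3344 ± 1351 for Smad6 and from 593 ± 98.5 to 5138 ± 935 for Smad7. Smad9, a BMP-activated SMAD, rose from 161 ± 14 to 517 ± 145. Nog, which encodes a secreted BMP antagonist, rose from 4.67 ± 2.31 to 157 ± 48.3. The list moved upward by limma camera with a preset inter-gene correlation of 0.01 (adjusted p = 9.1e-12), and not with an estimated correlation (adjusted p = 0.632 with an estimated correlation). It passed by fry (adjusted p = 0.0194), which does not compare the list with other genes. The call for Id4 was lost without control replicate 1 (adjusted p = 0.0577), control replicate 3 (0.0869), stimulated replicate 2 (0.0848), stimulated replicate 3 (0.121) or both replicate 2 libraries (0.0629) by limma. With the replicate block and all libraries, Id4 passed limma (adjusted p = 0.000459).

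Among BMP receptors, ligands and extracellular regulators, 11 of 35 members rose and 2 fell (11 and 6 adjusted over the list alone, 12 and 9 with the replicate block), and the list as a whole did not move (camera adjusted p = 0.132) except without stimulated replicate 1 (0.0404). Bmpr2, the type II BMP receptor gene, rose from 4632 ± 339 to 14860 ± 1627 (1.68 ± 0.11, limma adjusted p = 0.000469). Eng, the co-receptor endoglin, rose from 2582 ± 431 to 6219 ± 2804 (1.19 ± 0.30, limma adjusted p = 0.0439). That call was lost with equal library totals (0.0609) and without control replicate 1 (0.14), control replicate 2 (0.0616), control replicate 3 (0.136) or stimulated replicate 3 (0.129). With the replicate block and all libraries, Eng passed limma (adjusted p = 0.00178). Acvrl1, the type I receptor for BMP9 and BMP10, had a change of 0.06 ± 0.16 (limma adjusted p = 0.861). Fstl3, a secreted activin antagonist, rose by 2.20 ± 0.12, while the co-receptor genes Tgfbr3 and Rgma fell by 2.10 ± 0.13 and 2.96 ± 0.23. Exons of a gene on the opposite strand cover 47.3% of the exonic bases of Fstl3, so its level is uncertain.

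Part of the contractile apparatus rose. Of 35 genes on that list, 11 rose, none fell and 24 did not pass (13 rose when adjusted over the list alone), with a median log2 change of 0.57. Acta2, smooth muscle actin, on chromosome 19 from 34241090 to 34255590 in mm10, rose from 31090 ± 7140 to 109197 ± 42168 (1.76 ± 0.30, limma adjusted p = 0.0121). Tagln (926 ± 132 to 2966 ± 1176) and Cnn1 (846 ± 192 to 2573 ± 895), which encode the actin-binding proteins transgelin and calponin, rose by 1.61 ± 0.28 and 1.57 ± 0.27. The smallest p-values on the list belonged to Nexn (1.20 ± 0.13), Filip1l (1.21 ± 0.17) and Vcl (0.78 ± 0.11). Myh11, smooth muscle myosin heavy chain, was at 2684 ± 707 in controls and 3603 ± 1179 after stimulation (0.41 ± 0.27, limma adjusted p = 0.374). Myocd, a coactivator of contractile genes, was at 35.3 ± 18.6 and 50.7 ± 13.4 (0.60 ± 0.41, limma adjusted p = 0.386), and Smtn had a change of 0.57 ± 0.23 (limma adjusted p = 0.16; 0.0012 with the replicate block). With the replicate block, 20 members of the list rose and 1 fell. In stimulated samples, members were at a median of 1.52-fold in replicate 2 over the other replicates (31 of 35 higher), against 1.06-fold in controls (15 of 35), and the median log2 change was 0.44, 0.80 and 0.35 in pairs 1, 2 and 3. The list moved by camera (adjusted p = 4.2e-05), and neither with an estimated correlation (adjusted p = 0.759 with an estimated correlation) nor by fry (adjusted p = 0.198).

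The calls of Acta2, Tagln and Cnn1 were lost without some single libraries, while those of Nexn, Filip1l and Vcl were kept. The fits that leave out libraries did not use the replicate block. With the block and all libraries, Acta2, Tagln and Cnn1 passed limma (adjusted p = 0.000147, 0.00232 and 0.00121). By limma, Acta2 did not pass without control replicate 3 (log2 change 1.80, adjusted p = 0.0511) or stimulated replicate 3 (1.75, 0.0661). Tagln did not pass without control replicate 1 (0.0565) or stimulated replicate 3 (0.0686), with log2 changes of 1.55 or above, nor did Cnn1 (1.42, 0.0556 and 1.56, 0.0702), which was also not called without both replicate 2 libraries (1.29, 0.0643). Exons of genes on the opposite strand cover 67.9% of the exonic bases of Tagln and 25.5% of those of Vcl, so these levels are uncertain where counting ignored strand.

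**Figure D2:**
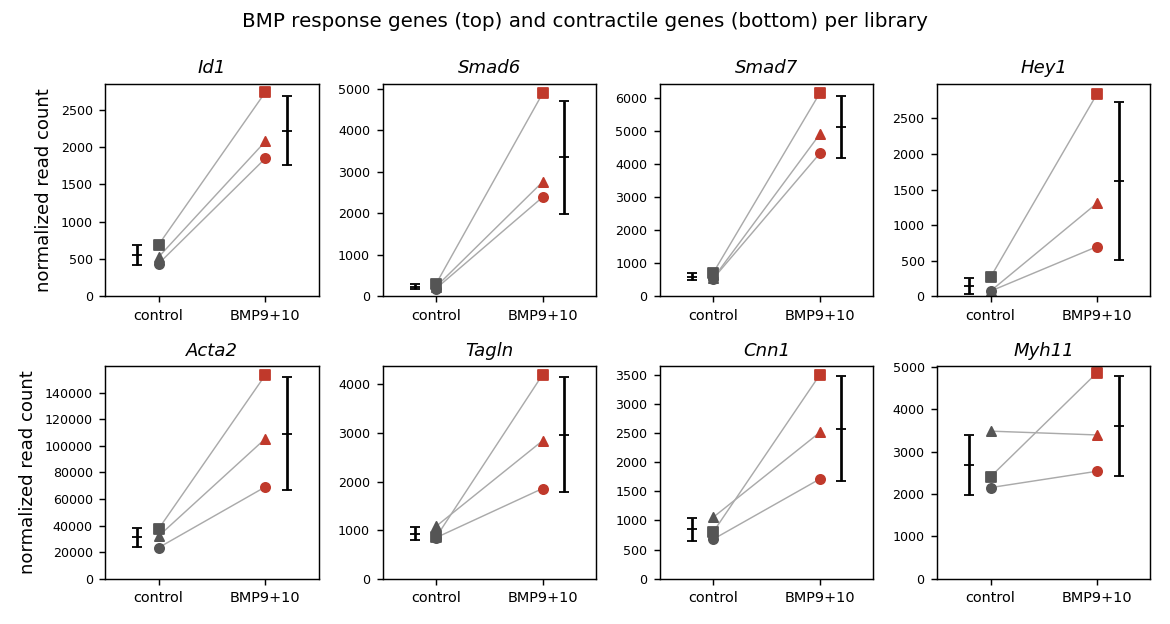
Normalized read counts (y axes, from 0) of 4 BMP response genes and 4 contractile genes in control and stimulated libraries; each symbol is 1 library, lines join libraries with the same replicate number, and bars show mean ± SD (n = 3). Acta2 was higher in each stimulated library than in each control, whereas Myh11 values of the groups overlapped.

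Of 17 transcriptional regulators of contractile genes, 3 rose and none fell (5 and 3 adjusted over the list alone, 6 and 3 with the replicate block; camera adjusted p = 0.27). Srf, serum response factor, rose from 1370 ± 301 to 3294 ± 669, and its coactivator Mrtfa rose by 0.63 ± 0.11 and Mef2a by 0.43 ± 0.11. Srf was not called by limma without stimulated replicate 3 (adjusted p = 0.0506), Mrtfa without control replicate 1 (0.0585), control replicate 3 (0.0541) or stimulated replicate 3 (0.0606), and Mef2a with equal library totals (0.185), upper-quartile factors (0.0681) or a pseudocount of 0.1 (0.0505), or when any of 5 libraries was left out. Smooth muscle and pericyte identity genes had 3 rises and no fall among 14 (6 and 2 with the replicate block), with Cspg4 at 1.77 ± 0.13, the cadherin gene Cdh6 at 2.95 ± 0.25 and the PDGF receptor gene Pdgfrb at 0.70 ± 0.08. That list did not move in the main test (camera adjusted p = 0.132) and moved with the block (0.0353), with equal library totals (0.0329), without control replicate 2 (0.0120) and without stimulated replicate 1 (0.0249). Among 43 ion channels and vasoactive receptors, 8 rose and 3 fell (12 and 13 with the replicate block). The serotonin receptor genes Htr1b (180 ± 19.9 to 1861 ± 508) and Htr2b (167 ± 26.6 to 586 ± 158) rose, and the endothelin receptor gene Ednrb fell by 1.42 ± 0.16. Camera found no shift of that list (adjusted p = 0.918).

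Most listed TGF-beta-SMAD2/3 response genes also rose. Of 29 members, 21 rose, 2 fell and 6 did not pass (21 and 3 adjusted over the list alone), and the mean log2 change was 1.17. Ccn2, a matricellular protein gene, went from 11550 ± 1842 to 119695 ± 14361 and Pmepa1 from 6104 ± 289 to 19458 ± 691. The falls, chosen after their values were seen, were Smad3 (-1.92 ± 0.11) and Snai2 (means of 930 and 467, limma adjusted p = 0.0116). The list moved by camera (adjusted p = 9.1e-12; adjusted p = 0.322 with an estimated correlation) and by fry (adjusted p = 0.00265). Extracellular matrix genes had 12 rises and 1 fall among 51 (16 and 6 with the replicate block), led by the hyaluronan synthase gene Has2 (644 ± 131 to 7870 ± 799), Lox (1.93 ± 0.10) and Thbs1 (1.72 ± 0.13). The matrix list's shift (camera adjusted p = 0.00483; adjusted p = 0.759 with an estimated correlation) was lost by fry (0.17), with a filter at 1 CPM in 3 libraries (0.0873), with equal totals and the replicate block (0.0578), without stimulated replicate 2 (0.195) and without both replicate 2 libraries (0.358). Exons on the opposite strand cover 23.2% of the exonic bases of Ccn2 and 21.3% of those of Timp3. Matrix proteases and inhibitors did not move as a list (camera adjusted p = 0.81), with 1 rise and 2 falls among 22 (4 and 6 with the replicate block). Timp3 rose by 1.40 ± 0.21, a call lost by limma without stimulated replicate 3 (adjusted p = 0.0535), and Adamts5 fell by 1.99 ± 0.20.

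Osteochondrogenic genes had 5 rises and no fall among 24 (6 and 4 with the replicate block), including Runx2, a transcription factor of bone formation (840 ± 90.9 to 1630 ± 261), Tnfrsf11b (2.25 ± 0.23) and Enpp1 (1.34 ± 0.14). The list passed camera narrowly (adjusted p = 0.0481; adjusted p = 0.759 with an estimated correlation), and not by fry (0.109), with a filter at 1 CPM in 3 libraries (0.251), with the replicate block (0.0889), without control replicate 1 (0.106) or without stimulated replicate 3 (0.085). Wnt pathway genes had 9 rises and 1 fall among 30 (14 and 3 with the replicate block; camera adjusted p = 0.00261, adjusted p = 0.759 with an estimated correlation, fry adjusted p = 0.0874). Wnt5a rose by 1.92 ± 0.11, Lef1 by 1.65 ± 0.18 and Fzd7 by 0.58 ± 0.07. YAP-TEAD response genes had 6 rises and no fall among 17 (camera adjusted p = 0.00376, adjusted p = 0.673 with an estimated correlation, fry adjusted p = 0.0843). Of these, Ankrd1 rose by 1.16 ± 0.20, a call lost by limma without control replicate 1 (adjusted p = 0.0506) or stimulated replicate 3 (0.0558), and Tead1 by 0.79 ± 0.13, lost without stimulated replicate 3 (0.0568) or both replicate 2 libraries (0.0606). Notch pathway genes did not move as a list (camera adjusted p = 0.391), with 4 rises and 1 fall among 18 (4 and 4 with the replicate block), while the Notch ligand gene Jag1 went from 1053 ± 413 to 9711 ± 762.

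Immediate early genes, which answer stimuli within minutes to hours, had 19 rises and 1 fall among 36, with Hbegf from 502 ± 94.3 to 9934 ± 1645, Ccn1 from 3460 ± 1076 to 28876 ± 4803 and Maff from 1189 ± 56.1 to 5557 ± 604. The list moved by camera (adjusted p = 5.3e-08, and adjusted p = 0.673 with an estimated correlation) and by fry (adjusted p = 0.0279). Hypoxia and glycolysis genes had 10 rises and 1 fall among 32 tested rows of 31 listed symbols (16 and 4 with the replicate block). That list moved by camera (adjusted p = 0.000662, and adjusted p = 0.673 with an estimated correlation) and by fry (adjusted p = 0.0279). Hexokinase 2 (Hk2) rose by 1.82 ± 0.11 and Vegfa by 1.30 ± 0.10, while Adm, adrenomedullin, fell from 2216 ± 212 to 438 ± 99. Cytokine, chemokine and NF-kappaB genes went both ways, with 7 rises and 7 falls among 45 (camera adjusted p = 0.391); the rises included Lif (3.15 ± 0.14), Il6 (35 ± 6.25 to 522 ± 91.9) and Csf1 (1.91 ± 0.11). Growth factors and their receptors had 9 rises and 6 falls among 42 (13 and 12 with the replicate block; camera adjusted p = 0.81), with Inhba, an activin subunit, from 4114 ± 279 to 26404 ± 175 and Fgf2 at 1.77 ± 0.16.

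Part of the interferon response genes fell. Of 36 members, none rose, 10 fell and 26 did not pass (18 fell when adjusted over the list alone, and 24 with the replicate block), with a median log2 change of -0.62. Cmpk2 went from 213 ± 44.5 to 33 ± 4.36, Tap1, a peptide transporter of antigen presentation, from 937 ± 83.8 to 537 ± 65.2 and Ddx58, the RNA sensor RIG-I, from 1471 ± 55.7 to 1069 ± 34.1. The list moved down by camera (adjusted p = 5.3e-08), and neither with an estimated correlation (adjusted p = 0.673 with an estimated correlation) nor by fry (adjusted p = 0.0843). Ddx58 was not called by limma without control replicate 1 (adjusted p = 0.0529), control replicate 3 (0.0607) or stimulated replicate 3 (0.0702). Cell cycle and DNA replication genes did not move as a list (camera adjusted p = 0.487; 0.0124, upward, without stimulated replicate 1, and downward without a call in 3 other settings), with 3 rises and 1 fall among 51 (10 and 4 with the replicate block); Mcm6, a replication helicase subunit, rose by 1.13 ± 0.16. Cholesterol biosynthesis genes (1 rise and 1 fall among 24, camera adjusted p = 0.898) did not move either. Unfolded protein and amino acid stress genes had 4 rises and 1 fall among 29, and the list did not pass camera (adjusted p = 0.0606) except with the replicate block (0.0193; 10 rises and 1 fall) and without stimulated replicate 1 (0.00221).

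Over all genes tested, the largest rises included those of Wnt1 (1.33 ± 0.577 to 118 ± 7, 5.70 ± 0.31), the cytokine gene Il11 (5.04 ± 0.30), the connexin gene Gja3 (4.63 ± 0.34), the complement-related C1qtnf3 (3.75 ± 0.45) and the vasopressin receptor gene Avpr1a (3.62 ± 0.32). Hey1 (3.63 ± 0.66) was not called by limma without control replicate 1 (adjusted p = 0.0608), control replicate 3 (0.0648) or stimulated replicate 3 (0.0733). The bile acid receptor gene Gpbar1 (3.86 ± 0.76) was not called without control replicate 3 (0.0698) or any of the 3 stimulated replicates (0.0538, 0.0511 and 0.0937). With the replicate block and all libraries, limma called both Hey1 (adjusted p = 7.6e-05) and Gpbar1 (0.00419). The largest falls included those of Palm3 (-3.43 ± 0.44), the tight junction gene Cldn1 (318 ± 43.4 to 34 ± 20, -3.40 ± 0.49), Spata25 (-3.30 ± 0.49), Apln, which encodes the peptide apelin (1673 ± 568 to 197 ± 52.2), and Mrgprf (-2.94 ± 0.25). Osr2 (-2.88 ± 0.41), Rspo2 (-2.77 ± 0.35), Dlgap2 (-2.69 ± 0.28) and Gpsm2 (-2.58 ± 0.23) followed.

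**Figure D3:**
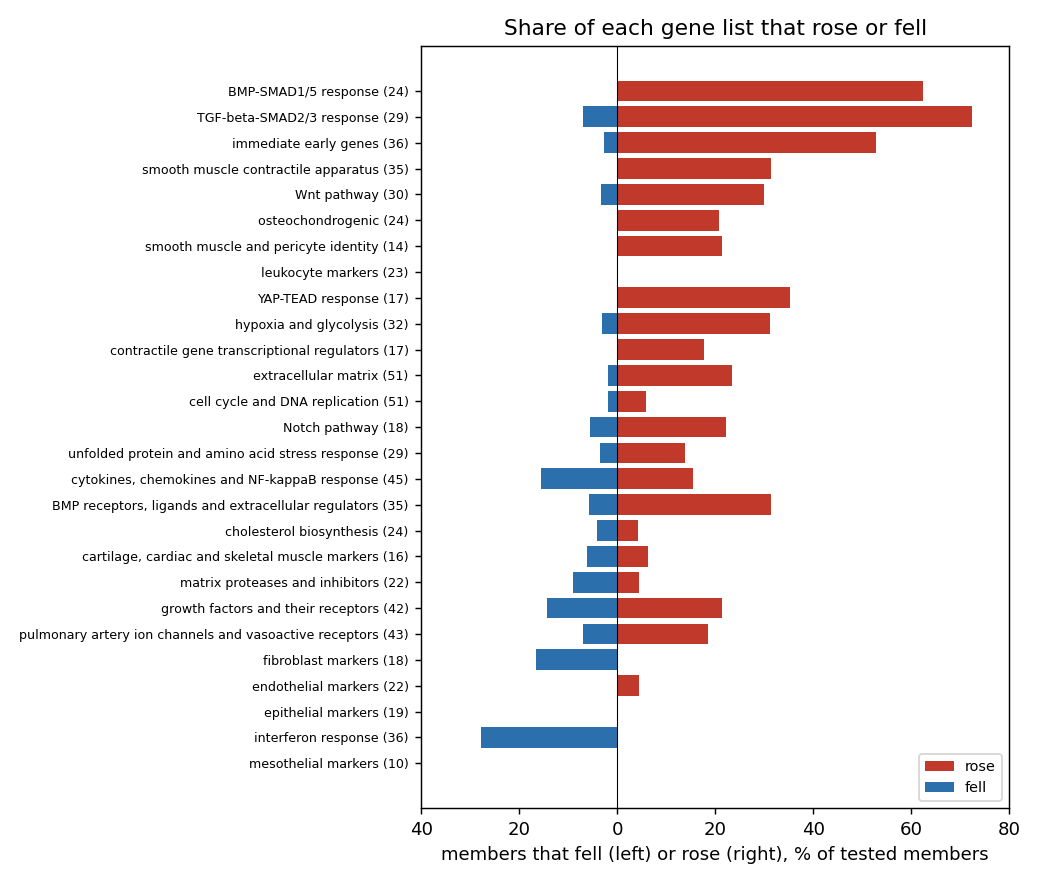
For each of the 27 gene lists (number of tested members in parentheses, ordered by median log2 change), bars give the percent of members that fell (blue, left) or rose (red, right) at an adjusted p under 0.05 by limma. Lists with 15 of 24 and 21 of 29 members rising are those of the BMP-SMAD1/5 and TGF-beta-SMAD2/3 responses, and 10 of 36 interferon response genes fell.

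The cultures held transcripts of other cell types, at levels that differed between replicate numbers. All 22 endothelial markers were highest in replicate 2 of both groups, at a median of 3.65-fold over the other replicates in controls and 3.63-fold in stimulated samples. Pecam1 was at 2126, 8731 and 2767 in control replicates 1 to 3 and at 2078, 9255 and 3066 in the stimulated ones. Epithelial and mesothelial markers were also higher in replicate 2 (3.91-fold and 6.98-fold in controls, 18 of 19 and all 10 markers highest there; 3.47-fold and 5.44-fold in stimulated samples, 13 of 19 and 8 of 10). The geometric mean of the epithelial markers was 557 in stimulated replicate 2 and 522 in stimulated replicate 3. Leukocyte markers were not set apart in this way (1.36-fold and 0.87-fold), though Lyz2, a macrophage gene, ranged from 81014 to 179899. No leukocyte, epithelial or mesothelial marker passed limma (23, 19 and 10 tested, of which 1, 2 and 0 had an unadjusted p under 0.05; camera adjusted p = 0.214, 0.214 and 0.391), and with the replicate block 2 rose and none fell, 2 rose and 3 fell, and none rose and 1 fell. Of 22 endothelial markers, the VEGF receptor gene Flt1 rose (1.55 ± 0.27, limma adjusted p = 0.0127), a call lost without control replicate 1 (0.0508), control replicate 3 (0.0563) or stimulated replicate 3 (0.0698). With the block 3 endothelial markers rose and 8 fell (camera adjusted p = 0.606 without the block and 0.0267 with it). Fibroblast markers had no rise and 3 falls among 18 (3 and 5 with the block; camera adjusted p = 0.286), with Pdgfra from 11353 ± 1950 to 4656 ± 978 and Fibin at -1.37 ± 0.13. Of 16 cartilage, cardiac and skeletal muscle markers, 1 rose and 1 fell (camera adjusted p = 0.916). Without both replicate 2 libraries, 2398 genes changed, 1505 higher and 893 lower, and by camera the leukocyte list moved up (adjusted p = 0.0489), as it did without control replicate 2 (0.0320). Without stimulated replicate 2, the epithelial, mesothelial and endothelial lists moved down by camera (adjusted p = 0.0335, 0.0209 and 0.0210). Control replicate 2 had the highest geometric mean of endothelial (1998), epithelial (1073), mesothelial (293) and leukocyte (1466) markers among the controls. Fits that drop a replicate 2 library from 1 group only are therefore unbalanced. Their shifts of these lists cannot be told apart from that imbalance.

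**Figure D4:**
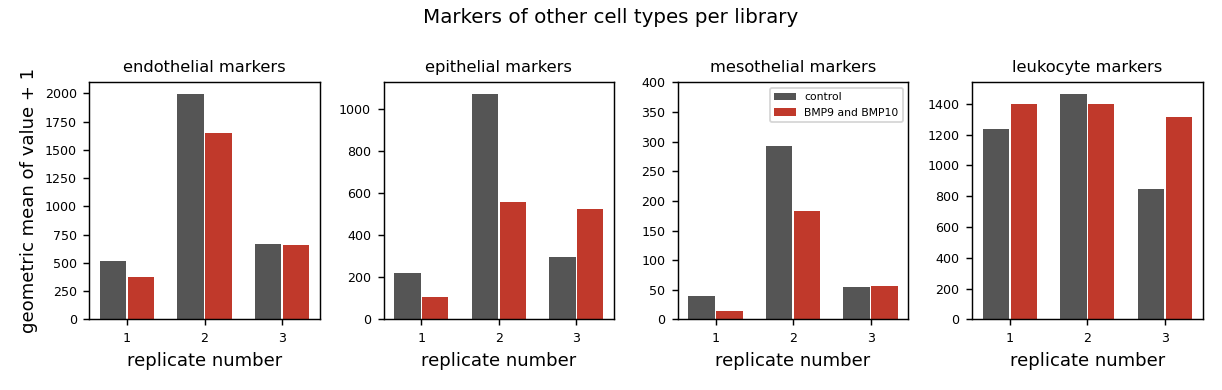
Bars give the geometric mean of value + 1 over the markers of each cell type (y axes, from 0, normalized read counts) in each library, by replicate number (x axis); grey is control and red is stimulated. Endothelial markers stand at 1998 and 1654 in the replicate 2 libraries and between 376 and 669 in the others.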

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

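No gene or list called in the main test changed direction under any alternative run. The count models planned for raw counts, edgeR and DESeq2, were not run because the values are normalized; the scalings were computed on the deposited values with limma, and the planned prior count of 0.5 for lists was run as a pseudocount. TMM scaling, the removal of both replicate 2 libraries and equal totals with the block were chosen after seeing the data.

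Against 2905 changed genes (1873 higher, 1032 lower), limma gave 5837 (3232 and 2605) with the replicate block, of which 2895 were shared and 10 of the original calls were lost. Equal totals gave 1135 higher and 2265 lower, and equal totals with the replicate block gave 6958 in all, 4916 of them lower. A threshold of 0.01 left 964 (722 and 242), and a log2 change of at least 1 left 946 (542 and 404). Leaving out 1 library gave 917 to 2384 changed genes, 659 to 1583 higher and 258 to 801 lower, with the lowest values without stimulated replicate 3; fewer samples were tested. Of 27 lists, 10 moved, 0 passed with an estimated correlation and 4 by fry; with 1 library left out, 9 to 14 of the 27 passed. The BMP-SMAD1/5 list had a camera adjusted p of 0.632 and the contractile list of 0.759 with an estimated correlation. The estimates were 0.307 and 0.553, against the preset 0.01. By fry the BMP-SMAD1/5 list had an adjusted p of 0.0194. The contractile list had one of 0.198 by fry, and the cause of that was not tested. Beyond the calls named in the report, the block turned the calls of Mrc1 (0.0126) and Foxj1 (0.0389) by limma. Among 102 named genes, 27 lost their call without stimulated replicate 3, 21 without control replicate 1 and 20 without control replicate 3. With the replicate block and all libraries, 99 of the named genes kept their result and 3 gained a call. Depth limits low genes most in stimulated replicate 1.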

Other observations

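Gene families in this and the next paragraph were picked after the results were seen. Ribosome biogenesis factors, which assemble ribosomal subunits, had 19 rises and 1 fall among 59 genes by limma (33 and 1 with the replicate block), with a median log2 change of 0.33, or 0.16 with equal library totals. Camera over 25 families gave an adjusted p of 3.7e-11, and an adjusted p of 0.408 with an estimated correlation. Among 170 small nucleolar RNAs, 9 rose and none fell, and 144 had a positive change (median 0.64, or 0.49 with equal totals). Of 20 aminoacyl-tRNA synthetase genes, 4 rose and none fell (median 0.28, or 0.11 with equal totals). The ribosomal protein genes had a median of -0.08 over 78 genes, or -0.26 with equal totals.

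Of 67 dynein heavy chain and cilia and flagella associated genes, 2 rose and 10 fell (2 and 16 with the replicate block), with a median of -0.72, or -0.89 with equal totals (camera adjusted p = 1.1e-05; adjusted p = 0.408 with an estimated correlation). Members of that family were picked by gene symbol. Some have names of neither kind, such as Spag9 among the rises and Ccdc40 and Rsph1 among the falls. Foxj1, a regulator of motile cilia on the epithelial marker list, was at 248, 297 and 80 in control replicates 1 to 3 and at 42, 55 and 75 in the stimulated ones (limma adjusted p = 0.0713). The epithelial list had median log2 changes of -1.25, -0.82 and 0.55 in pairs 1 to 3, so a smaller share of ciliated epithelial cells is not excluded. Semaphorins had no rise and 5 falls among 20 (median -0.30). Of 5 Dlx homeobox genes 4 rose, and of 8 serotonin receptor genes 3 rose.

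All tests of patterns below were chosen after the result was seen, except the comparison with other splits. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave 2905 changed genes by limma, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 6247 genes and the others up to 2533, or up to 307 where all 3 pairs were parted. With 10 splits the share cannot fall under 0.05. For gene lists, 7 of the 10 splits gave at least as many as the real 10, and the highest of the others gave 22. Splits that part all 3 pairs gave 5, 8 and 10. The splits that moved most lists keep 2 pairs together, which points to the structure by replicate number, so the number of moved lists by camera with a preset correlation does not set the stimulation apart from other groupings.

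The rise of the BMP-SMAD1/5 response genes came with endothelial transcripts in the cultures, and endothelial cells respond to BMP9. If they were the only source, the increase would be larger in pair 2 by about the 3.63-fold (3.30 to 3.91, 95% bootstrap interval over 22 markers) by which their markers were higher in control replicate 2. Over all 24 members of the list, the increase in pair 2 was a median of 1.65-fold that in the other pairs (1.22 to 2.21), with 18 ratios under 3.30. Both intervals are over genes, whose estimated correlations were 0.307 for the list and 0.949 for the markers. They do not cover the spread between pairs, and only pair 2 carries the endothelial excess. For these pairs the values argue against endothelial cells as the only source for the list, without excluding it. Ratios over 3.91 were those of Gata2, Tmem100, Fgfr3 and Msx1, named after their values were seen, and Bmper and Cdkn1a had no increase outside pair 2 and were counted above any bound. None of these 6 passed limma, and an endothelial source stays open for them. With equal library totals, the median log2 change of all 24 members of the list was 1.68 (0.89 to 2.31, 95% bootstrap interval over genes), against 1.85, so scaling does not account for the rise. A response of the PASMCs themselves is a candidate explanation. A part played by endothelial cells, or by the leukocytes whose markers were high in each library, stays open.

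With equal totals, the median log2 change of all 35 contractile genes was 0.40 (0.04 to 0.56, 95% bootstrap interval over genes), against 0.57, while that of all genes tested was -0.20; 10 members rose and none fell by limma. The interval treats the members as independent, though their estimated correlation was 0.553. It therefore cannot exclude scaling as the whole cause for the list's median. The 10 members that rose with equal totals were picked by that same result, so they give no separate evidence on scaling. The bound of 0 was set after the values were seen: an earlier test with a bound of 0.5, which the list's median does not reach, was set aside because it used only members that had risen. A larger share of smooth muscle cells in the stimulated libraries would lower markers of the other cell types alike. The medians of 5 such lists were above 0 in 4 of 15 comparisons by list and pair. Those of the fibroblast list (-0.17, -0.15 and -0.41) and the mesothelial list (-1.51, -0.35 and -0.23) were below 0 in each pair, as a larger share would give. The endothelial, leukocyte and epithelial lists were each above 0 in some pair. The leukocyte and mesothelial lists lay 0.97 ± 0.76 (SD, n = 3 pairs) apart, a difference under 2 times its SD. A change in cell share and a change within the cells therefore cannot be told apart here, since 3 pairs vary too much. A comparison of Acta2 with Myh11, Des, Itga8 and Synpo2 was also run and was set aside, because those genes had been picked after their values were seen.

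More genes rose than fell with the values as deposited. RLE scaling hardly changed the deposited values, whose median ratios to the geometric mean were already 1.005 to 1.008 in the libraries. Its share of rises is therefore not a separate check. The share that rose was 64.3% with RLE and 64.6% with TMM factors, near the 64.5% of the deposited values. It was 51.2% with upper-quartile factors and 33.4% with equal totals. The majority of rises may therefore come from the scaling. Without the deeper stimulated replicate 3 the share was 71.9%, so it did not fall. It was also higher without control replicate 1 (72.0%) or control replicate 3 (73.2%), which were not deeper. Those fits likewise called fewer genes, so the test cannot decide on depth as the reason. Whether stimulated cells hold more RNA in all was not tested.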
